A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

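RNA-seq libraries from wild-type and sir2 hst1 double-deletion yeast were compared, 2 libraries per genotype. The deposited values are FPKM per open reading frame, 1 file per library. Per the submitters' processing notes, TopHat2 2.0.10 and Cuffnorm 2.2.1 were used. The genome build, the annotation, the scaling between libraries, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies, therefore cannot be separated.

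Each file listed 6690 systematic names. Of these, 6007 matched a locus tag of the R64 annotation and took its gene symbol, and 683 did not match and kept the systematic name. R64 was used only for names, neighbouring genes, distance to the chromosome end and upstream sequence, and no coordinates are given because the build of the files is not stated. Genes were called near-identical copies where blastn 2.17.0 aligned their coding sequences at 95% identity or more over at least 50% of the length, which held for 343 genes.

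FPKM values carry no read totals, so absolute depth is unknown. Where a gene's low value is a whole multiple of what 1 read is worth, the ratio of low values between libraries falls on steps. Steps within 0.01 on the log2 scale held for 22.5%, 21.5% and 27.3% of 187, 135 and 128 low genes in wild-type replicate 2 and deletion replicates 1 and 2, against 2.67%, 2.96% and 2.34% at the median offset, and gave the relative depths. Too few values fell on steps to recover whole reads, and no count test was run. In all 4 libraries 175 names were listed at 0, and 229, 264, 202 and 205 in each library. The 10 highest names took between 38.9% and 40.9% of the FPKM sum of a library. No nonzero value was identical between replicates.

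Genes with at least 1 FPKM in at least 2 libraries were tested, 6370 in all, and 320 were not. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with eBayes and a mean-variance trend (prior degrees of freedom 2.65), genotype as the only term and Benjamini-Hochberg adjustment. A log2 difference on this scale understates the change of low genes. Folds printed for single genes are ratios of mean FPKM, whereas counts of genes changed at least 2-fold use a log2(FPKM + 1) difference of 1. No fold is given against a genotype listed at 0, because a listed 0 can be a failed estimate, nor for genes with a mean under 2 FPKM in either genotype. Other genes are given as folds, levels or both. At an unadjusted p under 0.05, 1925 genes differed. The test was checked on simulated data for this comparison with 6287 genes, of which 200 were changed. It recovered 60%, 87.8%, 91.8% and 96% of genes changed 1.5-, 2-, 4- and 8-fold, called 8 unchanged genes and gave 0 wrong directions. The simulation gave each gene the same spread in both genotypes. In the data the log2 difference between replicates had a median absolute deviation of 0.0954 in wild type and 0.1465 in the deletion strain. The check also says nothing of false calls between cultures.

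Gene lists were fixed before the data were examined, and 27 with at least 3 tested genes went into limma's camera with a preset correlation of 0.01, adjusted over the lists. By camera 9 lists were higher and 2 were lower, and fry, which tests whether a list's genes move one way on balance, also gave 9 and 2, with the a-specific list in place of the galactose list. With an estimated correlation 0 lists were higher or lower by camera, with 2 higher and 0 lower at an unadjusted p under 0.05. Camera then uses the few residual degrees of freedom that 4 libraries leave, so a list could hardly pass. The subtelomeric list had an estimated correlation of -1e-04, below the preset, yet its unadjusted camera p went from 1.77e-07 to 0.0138. Adjusted p-values with an estimated correlation are therefore no measure of correlation between genes alone. The 2 deleted genes, the 6 mating-type genes and 8 Y' element helicase genes were too few or not tested. No list of Ty elements was formed, as the names in these files include none, and 3 listed genes were not found.

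The genes named in the text were chosen by a rule fixed before the data were examined. It took every member of the lists of deleted genes, their neighbours, markers and mating-type genes, and the 12 genes with the largest rise and the 12 with the largest fall among those past the adjusted p, with separate genotypes and a mean of at least 5 FPKM in the higher genotype. It also took up to 4 genes per list by size of change. BNA3, BNA5, BNA6, BNA7, NDT80, AGA1 and PHO3 fall outside the rule and were named after their values were seen. The alternatives tried were other pseudocounts, filters, scalings and eBayes options, the replicate number as a block, and leaving out each library, where the lone library is assumed to vary like the other genotype. Tests on R64 names only, without near-identical copies and with both restrictions, and a crossed block, were added after the data were seen. Tables and figures used Python 3.11.15 and scipy 1.17.1.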

Results

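RNA was sequenced from Saccharomyces cerevisiae grown exponentially in rich glucose medium, from a wild-type strain and a strain lacking both SIR2 and HST1. SIR2 and HST1 encode paralogous NAD+-dependent deacetylases. Sir2 acts in silencing at the mating-type loci, telomeres and ribosomal DNA, and Hst1 acts with the DNA-binding repressor Sum1. Both strains were of the alpha mating type and carried a replaced HMR locus. Each genotype had 2 libraries, which the series describes as technical replicates, so limma p-values of single genes measured only the spread between these libraries. Camera p-values at the preset correlation, and those of Fisher's and permutation tests, compared genes with other genes. None of them measured the spread between cultures. Each library gave 1 FPKM value for each of 6690 open reading frames. FPKM values summed to 3468679 and 3419038 in the wild-type libraries and to 3586265 and 3662426 in the deletion libraries, with medians between 36.9 and 37.3. These files do not hold read totals. Steps among the lowest values put the depth of wild-type replicate 2 at 89.5% of that of wild-type replicate 1, and the deletion replicates 1 and 2 at 82.4% and 77.4%. Pearson's correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.99 within each genotype and between 0.96 and 0.97 across genotypes.

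The comparison asked which genes changed expression when both deacetylases were missing. SIR2 was listed at 24.3 and 23.8 FPKM in the wild-type libraries and at 0 in both deletion libraries (limma, adjusted p = 0.000117). HST1 was listed at 58.2 and 57.8 FPKM in wild type and likewise at 0 in both deletion libraries (adjusted p = 9.35e-05). Among the neighbours of the deleted genes, the dubious reading frame YDL041W was listed at 4.33 and 15.1 FPKM in wild type and at 0 in the deletion libraries (adjusted p = 0.035). NAT1 (74.0 and 73.6 FPKM in wild type and deletion), PRP11 (55.4 and 62.2), RTG1 (39.1 and 43.2) and NUF2 (16 and 13.7) did not pass. TRP1, the gene that replaced SIR2, rose 4.68-fold, from 30.3 ± 1.03 to 142 ± 10.8 FPKM (mean ± SD, n = 2 per genotype, adjusted p = 0.000275). Any effect of this marker on other genes cannot be told apart from the loss of SIR2 and HST1. The markers URA3 and HIS3 fell by 0.31 and 0.42 on the log2 scale (adjusted p = 0.0309 and 0.0246). LEU2 (665 and 655 FPKM), CAN1 (88.5 and 78.9) and LYS2 (23.8 and 25.9) did not pass, although the labels of both strains give LYS2 as deleted.

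Expression differed in 608 of the 6370 genes tested, and more genes rose than fell. In the deletion strain 430 genes were higher and 178 were lower (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). A difference of at least 1 in log2(FPKM + 1), called at least 2-fold here, was reached by 211 of the higher genes and 12 of the lower genes. Of these 12, 7 are not in R64, and the 5 in R64 were SIR2, HST1, YGP1, CTT1 and ADE17. YBR200W-A had the largest rise, from 3.89 ± 2.11 to 572 ± 41.6 FPKM (log2 difference 6.94, SE 0.31, adjusted p = 0.000544). Next came 3 genes that were almost silent in wild type. LDS1, which acts in spore wall assembly, went from 1.18 ± 0.03 to 95.3 ± 0.82 FPKM, PFS1, a prospore membrane gene, from 0.774 ± 0.474 to 74.4 ± 3.63, and YGL138C from 0.816 ± 0.364 to 71.5 ± 3.55. SPR2, a sporulation gene, went from 0.81 ± 0.311 to 61.8 ± 3.03 FPKM, and SRL4 from 0.614 ± 0.282 to 48.9 ± 1.84. YOR011W-A and ANS1 rose by 4.80 and 4.92 on the log2 scale. Quantile normalization gave 355 higher and 294 lower genes, so 54.7% of the calls were higher, against 70.7% in the main test. Leaving out deletion replicate 1 or 2 left 190 or 184 genes higher and 121 or 125 of them at least 2-fold. The lower genes numbered 54, 50, 47 and 83 without wild-type replicate 1, wild-type replicate 2, deletion replicate 1 and deletion replicate 2, and those at least 2-fold lower numbered 7 without wild-type replicate 2. With only names in R64 tested, 297 genes were lower and 6 were at least 2-fold lower.

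**Figure D1:**
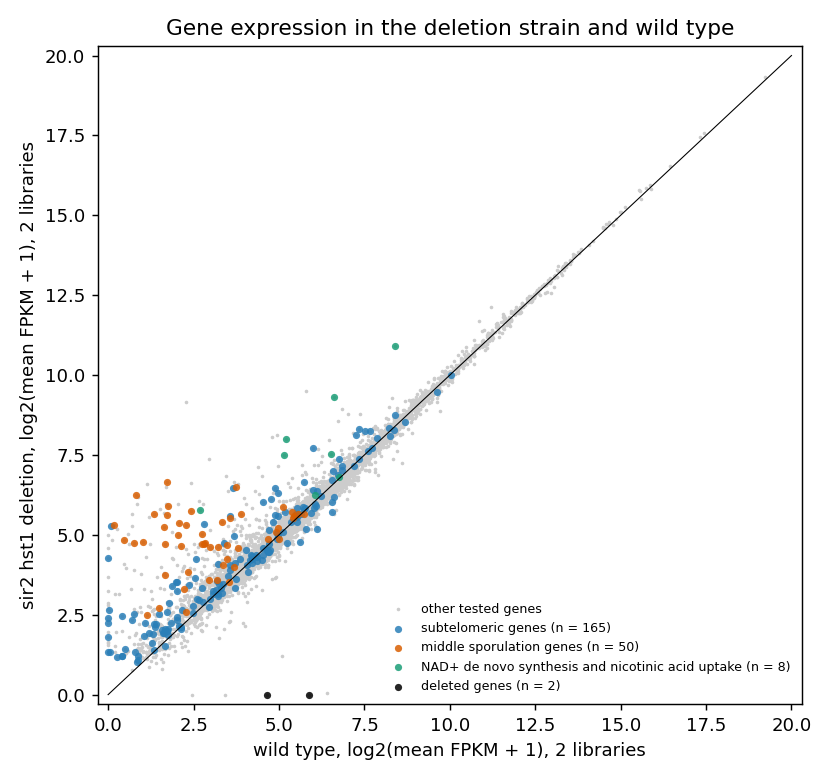
Gene expression in the deletion strain against wild type, each axis log2 of the mean FPKM of 2 libraries plus 1. The diagonal marks equal expression. Middle sporulation genes (orange, 50), NAD+ genes (green, 8) and some of the 165 subtelomeric genes (blue) lie above it, and the 2 deleted genes (black) lie at 0 on the vertical axis.

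Most genes of de novo NAD+ synthesis and nicotinic acid uptake rose, 6 of the 8 tested. BNA2, whose product catalyses the first step from tryptophan, rose 9.95-fold from 5.41 ± 0.55 to 53.9 ± 6.96 FPKM (mean ± SD, n = 2; log2 difference 3.09, SE 0.12, limma adjusted p = 0.000382). BNA4 rose 7.11-fold, BNA1 6.58-fold and the nicotinic acid permease gene TNA1 5.69-fold, the last from 338 ± 4.47 to 1921 ± 100 FPKM. Of the 8 members tested 6 rose and 0 fell (limma, with 0 also lower at an unadjusted p under 0.05), and 6 rose when adjusted over the list alone. The other risers were BNA5 (5.26-fold) and BNA6 (2.04-fold), while BNA3 (64.9 and 74.7 FPKM) and BNA7 (106 and 110 FPKM) did not pass. The list's median log2 difference was 2.43 (camera adjusted p = 5.4e-08; adjusted p = 0.297 with an estimated correlation). The NAD+ salvage list did not move as a group (camera adjusted p = 0.718; camera pointed down, while the median of 0.01 and mean of 0.05 lay above 0). In it NRT1, a nicotinamide riboside transporter gene, rose 3.01-fold from 28.7 ± 0.12 to 86.1 ± 4.37 FPKM. PNC1, the nicotinamidase gene, PHO8 and ISN1 fell by 0.46, 0.48 and 0.46 on the log2 scale. Adjusted over the list alone, 3 of its 12 genes were higher and 3 lower.

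**Figure D2:**
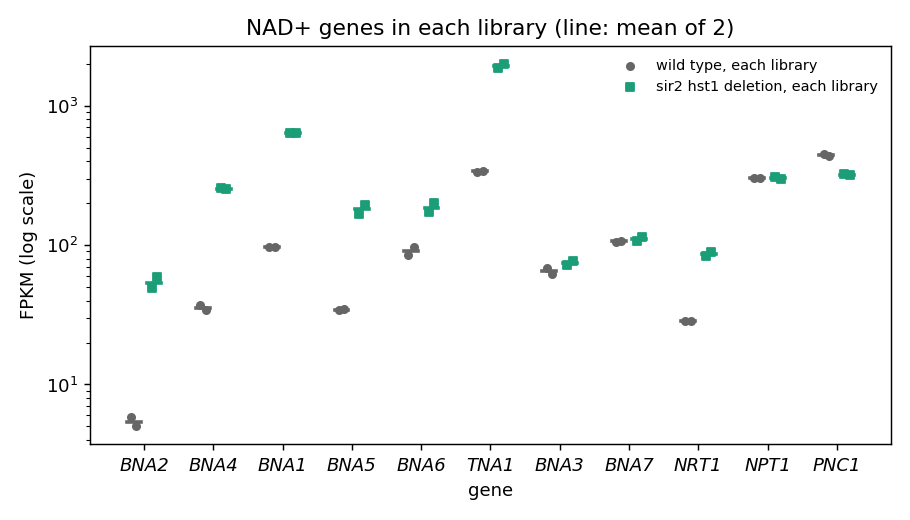
FPKM of NAD+ genes in each library on a log axis, with points for the 2 wild-type (grey) and 2 deletion (green) libraries and a line at each mean. Both deletion libraries lie above both wild-type libraries for BNA1, BNA2, BNA4, BNA5, BNA6, TNA1 and NRT1, and below them for PNC1. They also lie above for BNA3, which did not pass.

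Most genes normally expressed in the middle of sporulation rose, and this list had the smallest camera p at the preset correlation. Of 50 middle sporulation genes 37 rose and 0 fell (limma, with 0 lower at an unadjusted p under 0.05), and 40 rose when adjusted over the list alone. PFS1 led the list, followed by the chitin deacetylase genes of the spore wall. CDA2 was listed at 0.119 ± 0.024 FPKM in wild type and 38.3 ± 2.66 in the deletion strain (log2 difference 5.13, SE 0.11, limma adjusted p = 9.87e-05). CDA1 went from 2.32 ± 0.47 to 100 ± 0.46 FPKM, and OSW1, a spore wall gene, from 0.387 ± 0.047 to 27.6 ± 0.93 FPKM (n = 2 each). The median log2 difference of the list was 1.71 (camera adjusted p = 5.87e-29; adjusted p = 0.295 with an estimated correlation). NDT80, which encodes the activator of this programme, had 24.6 ± 1.97 FPKM in wild type and 28.4 ± 1.71 in the deletion strain and did not pass (adjusted p = 0.201). Early meiotic genes had a median log2 difference of 0.24 and did not pass as a list (camera adjusted p = 0.0595). That list passed without wild-type replicate 1 (adjusted p = 0.0492) or deletion replicate 2 (0.032), without the filter (0.0477), without the trend (0.0308) and with only names in R64 (0.0433), and its median was -0.15 after quantile normalization. The meiotic recombination genes MSH4 (3.90 ± 0.53 to 9.75 ± 1.30 FPKM) and DMC1 (5.74 ± 0.18 to 10.4 ± 0.41 FPKM) were the 2 of 28 members that rose, and 3 rose when adjusted over the list alone.

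**Figure D3:**
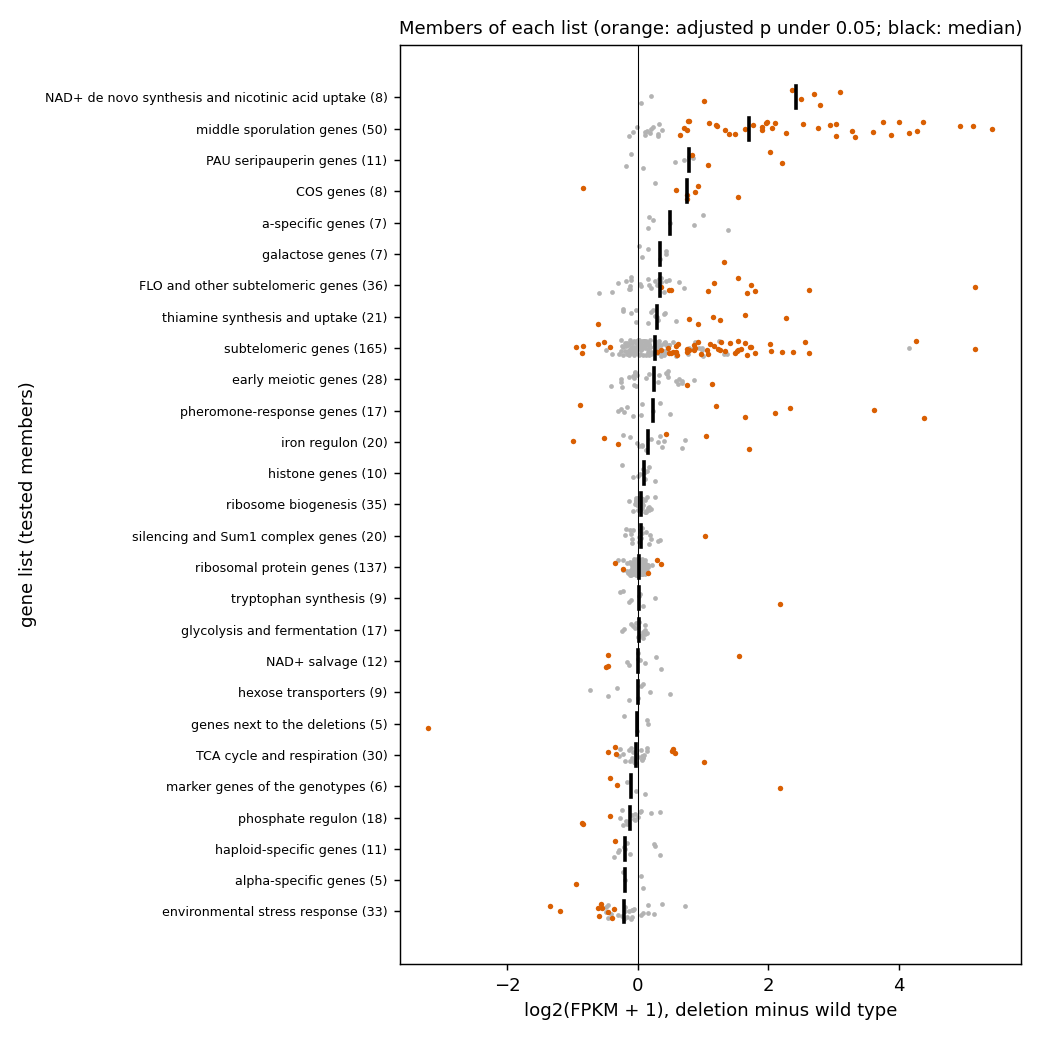
Log2 difference in FPKM + 1, deletion minus wild type, of each tested member of the 27 gene lists, with members past an adjusted p of 0.05 in orange and each list's median as a black bar. NAD+ de novo synthesis and middle sporulation genes have the highest medians, 2.43 and 1.71, and environmental stress genes the lowest, -0.21.

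Genes near chromosome ends were higher more often than genes elsewhere. Of 165 tested genes within 20 kb of an end in the R64 assembly 45 rose and 6 fell, and 57 rose and 10 fell when adjusted over the list alone. YFR057W, an uncharacterized gene next to a chromosome end, was listed at 0.132 and 0 FPKM in wild type and at 35.7 and 39.2 in the deletion libraries (limma, adjusted p = 0.000107). YOL166W-A was listed at 0 in both wild-type libraries and averaged 18.5 ± 4.32 FPKM in the deletion libraries, and YOL160W went from 6.03 ± 2.10 to 39.6 ± 3.72 FPKM. The subtelomeric median log2 difference was 0.26 (camera adjusted p = 1.59e-06; adjusted p = 0.295 with an estimated correlation). It was 0.02 after quantile normalization, 0.13 with a minimum of 5 FPKM, 0.15 with a pseudocount of 5 or without near-identical copies and 0.16 without deletion replicate 2, and the list passed in each case. Within 5 kb of an end 11 of 23 genes rose, between 5 and 10 kb 17 of 36, between 10 and 15 kb 13 of 51, and between 15 and 20 kb 4 of 55. In the FLO list, 36 genes of flocculation and other subtelomeric families, 11 rose and 0 fell (limma, with 3 lower at an unadjusted p under 0.05). No FLO gene was among the 11 that rose. Adjusted over the list alone 14 rose and 2 fell. It shared 22 tested genes with the subtelomeric list and passed (camera adjusted p = 0.000257; adjusted p = 0.297 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0807). IMD2 of guanine nucleotide synthesis rose 3.37-fold, from 62.2 ± 5.08 to 210 ± 27.7 FPKM.

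**Figure D4:**
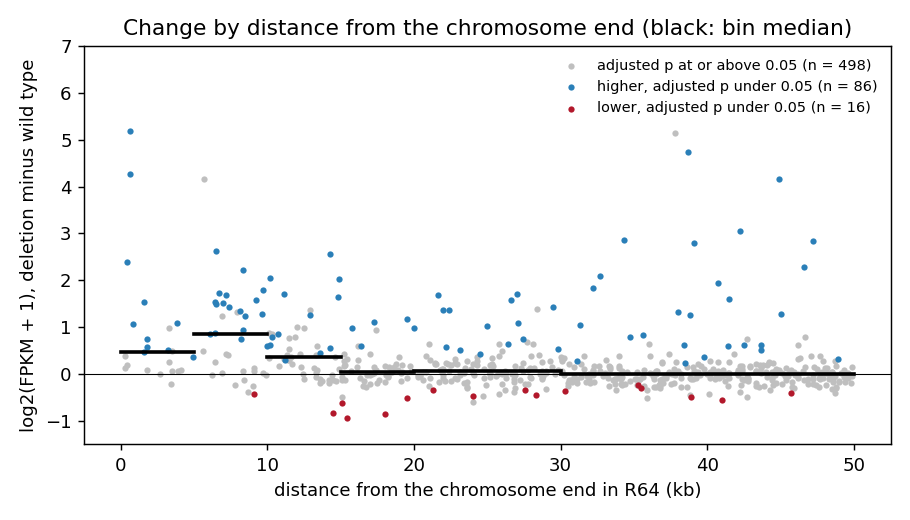
Log2 difference in FPKM + 1, deletion minus wild type, of genes up to 50 kb from a chromosome end by distance from that end in kb, with higher genes in blue, lower genes in red, the rest in grey and bin medians as black lines. The medians are 0.47, 0.86 and 0.36 in the 3 bins up to 15 kb and 0.04 between 15 and 20 kb.

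COS genes, a subtelomeric family of membrane proteins, mostly rose. Of 8 tested, 6 rose and COS9 fell, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000235; adjusted p = 0.304 with an estimated correlation). COS8 went from 151 ± 2.46 to 277 ± 7.19 FPKM and COS9 from 48.0 ± 2.38 to 26.3 ± 1.27. COS1 went from 52.0 ± 1.15 to 99.8 ± 1.96 and COS4 from 2.67 ± 0.51 to 9.65 ± 1.02, but these are near-identical to COS2 and COS3 and may share reads. Of 11 tested PAU genes, a seripauperin family, 4 rose and 0 fell (limma, with 0 lower at an unadjusted p under 0.05), and 5 rose when adjusted over the list alone. PAU17 went from 8.76 ± 1.91 to 16.2 ± 1.59 FPKM, PAU4 from 0.338 ± 0.183 to 4.45 ± 0.59 and PAU24 from 2.42 ± 0.12 to 6.25 ± 0.79. PAU10 was listed at 0 in wild type and at 4.79 and 2.71 in the deletion libraries. PAU4, PAU24 and PAU10 have near-identical copies in the family and may share reads. PAU17, for which no such copy was found, lies 94.7 kb from a chromosome end in R64. The PAU list passed (camera adjusted p = 0.012; adjusted p = 0.304 with an estimated correlation). Without genes that have a near-identical copy fewer members were tested, and neither COS (median 0.50 against 0.75, adjusted p = 0.16) nor PAU genes (median 0.72 against 0.79, adjusted p = 0.311) passed. The PAU list also missed the threshold without deletion replicate 1 (0.429) or 2 (0.129), after quantile normalization (0.102) and with a minimum of 5 FPKM (0.158).

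At the silent mating-type locus HML, the genes HMLALPHA1 and HMLALPHA2 were listed at 0 in all 4 libraries. MATALPHA1, MATALPHA2, HMRA1 and HMRA2 were listed at 0 as well, including the MAT genes that an alpha strain expresses, so these 0s give no expression level. YCL065W, a dubious reading frame absent from R64, so that its position was not checked here, was listed at 0 in both wild-type libraries and at 33.8 and 28.5 FPKM in the deletion libraries (limma, adjusted p = 0.000133). Toward the chromosome end from HML, VBA3 was listed at 0 in wild type and at 2.54 and 2.43 FPKM in the deletion libraries. GEX1 was listed at 0.0202 and 0 FPKM in wild type and at 5.74 and 4.80 in the deletion libraries. VBA3 and GEX1 have the near-identical copies VBA5 and GEX2.

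Genes of the pheromone response split into some that rose and one that fell. Of 17 tested 6 rose, and AGA1 fell by 0.88 on the log2 scale. Adjusted over the list alone 8 rose and 4 fell. FIG1, needed for efficient mating, went from 1.30 ± 0.75 to 45.8 ± 1.16 FPKM (log2 difference 4.39, SE 0.24, limma adjusted p = 0.0011) and PRM6 from 0.393 ± 0.184 to 16.2 ± 0.68 FPKM. The cell fusion gene FUS2 rose 6.57-fold and PRM2 5.08-fold (n = 2 each). The list passed (camera adjusted p = 0.0365; adjusted p = 0.323 with an estimated correlation), but not without deletion replicate 1 (adjusted p = 0.174) or 2 (0.176), after quantile normalization (0.0708) or without near-identical copies (0.0535). SAG1, the alpha-agglutinin gene, fell 1.94-fold from 319 ± 22.1 to 165 ± 9.01 FPKM, the 1 of 5 alpha-specific genes to pass (2 were lower when adjusted over the list alone; camera adjusted p = 0.158). No a-specific gene passed among 7 (limma, with 2 higher at an unadjusted p under 0.05; 1 when adjusted over the list alone; camera adjusted p = 0.0595). As a list they passed by fry (adjusted p = 0.0108), with the replicate block (camera adjusted p = 0.0311) or crossed block (0.0496), without the filter (0.0477), without the trend (0.0308), with only names in R64 (0.0433) and without wild-type replicate 1 (0.00381). Their values included 34.0 ± 18.3 and 64.6 ± 5.06 FPKM for the a-factor gene MFA2, while MFA1 was listed at 35.3 and 0 in the wild-type libraries. Of 11 haploid-specific genes 1, AXL1, fell, and 3 were higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.137).

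Thiamine genes included 6 that rose and 1, PHO3, that fell among 21 tested, with 8 higher and 1 lower when adjusted over the list alone. THI4, of thiazole synthesis, rose 5.83-fold from 3.84 ± 0.14 to 22.4 ± 0.71 FPKM (limma adjusted p = 0.000312) and the transporter-like gene THI73 2.36-fold. THI12 and THI5, which are near-identical to THI11 and THI13, averaged 4.06 ± 0.60 and 1.5 ± 0.11 FPKM in the deletion strain against 0.629 ± 0.374 and 0.041 ± 0.057 in wild type. The list passed (median log2 difference 0.29, camera adjusted p = 0.0121; adjusted p = 0.304 with an estimated correlation). It did not pass without deletion replicate 1 (adjusted p = 0.105) or 2 (0.108), without genes that have a near-identical copy (0.31), with a minimum of 5 FPKM (0.171) or after quantile normalization, which put its median at -0.04 (0.392). Among 7 galactose genes GAL7 rose 2.82-fold, from 4.30 ± 0.73 to 12.2 ± 0.78 FPKM, with 3 higher when adjusted over the list alone (camera adjusted p = 0.0289; adjusted p = 0.564 with an estimated correlation). That list did not pass without wild-type replicate 1 (0.0511) or deletion replicate 2 (0.108), after quantile normalization (0.367) or by fry (0.0967).

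Some environmental stress genes fell. Of 33 tested 9 fell and 0 rose (limma, with 2 higher at an unadjusted p under 0.05), and 14 fell and 2 rose when adjusted over the list alone. YGP1, which encodes a secreted glycoprotein, fell 2.55-fold from 387 ± 1.11 to 152 ± 6.43 FPKM (log2 difference -1.34, SE 0.05, limma adjusted p = 0.000438). The catalase gene CTT1 fell 2.41-fold from 26.9 ± 1.58 to 11.2 ± 0.35 FPKM, PGM2 1.56-fold and the trehalose synthesis gene TPS2 1.51-fold (n = 2 each). The median log2 difference was -0.21 (camera adjusted p = 7.95e-05; adjusted p = 0.297 with an estimated correlation) and -0.31 without deletion replicate 2. Of 18 phosphate regulon genes 3 fell and 0 rose (limma, with 2 higher at an unadjusted p under 0.05), and 6 fell and 1 rose when adjusted over the list alone. The acid phosphatase gene PHO5 fell from 844 ± 93.2 to 469 ± 25.9 FPKM, GIT1 from 93.5 ± 2.41 to 51.1 ± 0.10, and PHO12, near-identical to PHO11, from 97.7 ± 6.85 to 72.1 ± 3.4. The phosphate list passed (camera adjusted p = 0.0228; adjusted p = 0.306 with an estimated correlation), but not without deletion replicate 1 (adjusted p = 0.107) or without genes that have a near-identical copy (0.0761).

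Besides SIR2 and HST1, the largest listed falls were in small reading frames absent from the R64 annotation. YBR223W-A was listed at 60.7 and 54.0 FPKM in wild type and YOR161W-A at 112 and 56.8, against 1.08e-05 and 4.86e-05 and against 0.093 and 0.000227 in the deletion libraries. Values this close to 0 are not measured levels, so the sizes of these falls are uncertain. YMR316C-B fell from 14.5 ± 2.42 to 3.69 ± 0.16 FPKM. ADE17 of purine synthesis fell 2.01-fold from 236 ± 14.9 to 117 ± 11.8 FPKM, and the heme oxygenase gene HMX1 fell 2.03-fold (limma adjusted p = 0.00585 and 0.0223).

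Other lists did not pass as groups. In the TCA cycle list, CIT2 rose 2.02-fold from 144 ± 12.6 to 291 ± 22.6 FPKM, and ACO1, IDH1 and IDH2 rose 1.48-, 1.44- and 1.45-fold, while 3 of the 30 members fell (camera adjusted p = 0.753; median -0.03, mean 0.02; 4 higher and 4 lower when adjusted over the list alone). In the iron regulon FIT1 rose from 1.44 ± 0.28 to 6.94 ± 1.27 FPKM and FIT2 rose 2.07-fold, and 3 of 20 members rose and 3 fell (camera adjusted p = 0.153, and 0.0155 without wild-type replicate 1; 6 and 4 when adjusted over the list alone). Among 20 silencing and Sum1 complex genes ABF1 rose 2.14-fold from 9.44 ± 0.47 to 20.2 ± 1.28 FPKM and was the 1 to pass, with 2 when adjusted over the list alone (camera adjusted p = 0.418). SUM1 had 23.4 ± 1.29 and 30.0 ± 0.69 FPKM (limma adjusted p = 0.0501). Of 137 ribosomal protein genes 3 rose and 2 fell, and 0 passed when adjusted over the list alone (limma, with 16 higher and 12 lower at an unadjusted p under 0.05; camera adjusted p = 0.258, and 0.00046 without deletion replicate 1). No member passed among 35 ribosome biogenesis genes (limma, with 3 at an unadjusted p under 0.05; camera adjusted p = 0.153), 17 glycolysis genes (0; 0.927), 10 histone genes (4; 0.366) or 9 hexose transporters (5; 0.646). Adjusted over the list alone, these counts were 0, 0, 2 and 3. Single libraries decided some of these list results. The glycolysis list passed upward without deletion replicate 1 (median 0.12, camera adjusted p = 0.00106) and downward without deletion replicate 2 (median -0.07, 0.00525), and the histone list passed upward without deletion replicate 1 (0.0383). Among 9 tryptophan synthesis genes only the marker TRP1 passed, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.971, pointing down with a median of 0.02 and a mean of 0.21). The marker genes (camera adjusted p = 0.685; pointing down with a median of -0.10 and a mean of 0.23; 1 higher and 2 lower when adjusted over the list alone) and the neighbours of the deletions (0.685; 1 lower) did not pass as lists.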

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

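The tests on R64 names only, without near-identical copies and with both restrictions, and the crossed block were chosen after the data were seen. No gene at least 2-fold changed in the main test had the opposite sign under any alternative in which it was tested. The middle sporulation, NAD+ de novo, subtelomeric and stress lists passed under every alternative with the preset correlation. A pseudocount of 5 left 6 genes at least 2-fold lower. Quantile normalization gave 294 lower genes, 23 at least 2-fold lower and 4 higher lists. With R64 names only 297 genes were lower, 6 at least 2-fold. Without near-identical copies 178 genes were lower, 12 at least 2-fold, and 5 lists were higher and 1 lower. With both restrictions 308 genes were lower, 6 at least 2-fold, and 1 list was lower. With an estimated correlation 0 lists were higher and 0 lower (2 and 0 at an unadjusted p under 0.05). Causes were not tested, except that a larger pseudocount shrinks differences of low genes and that camera with an estimated correlation has few degrees of freedom. Leaving out 1 library gave 184 to 377 genes higher, 47 to 83 lower, 121 to 249 at least 2-fold higher and 7 to 15 at least 2-fold lower, with 6 to 11 lists higher and 1 to 3 lower. These fits rest on fewer libraries. The glycolysis median ranged from -0.0746 without deletion replicate 2 to 0.12 without deletion replicate 1 and passed in both directions (adjusted p = 0.00525 and 0.00106), and the difference of MFA1 from -1.21 without wild-type replicate 2, where it was listed at 0, to 3.98 without wild-type replicate 1. The replicate number as a block gave 360 higher and 111 lower genes. Deviations of same-numbered libraries had Pearson correlations of -0.09 over all tested genes and -0.22 over genes with a mean of at least 20 FPKM. Spearman's correlations were 0.0495 and 0.0459. Pairing by number was therefore not evident, though 4 libraries cannot exclude it. Crossed pairing gave 400 higher and 120 lower genes. Counts of genes and lists stayed within 1.5 times the main count in 82 cases, rose in 4 and dropped in 20. Named genes stayed on the same side of the threshold with the same direction in 1827 cases, whether called or not, gained a call in 54 and lost it in 126, changed sign without a call in 8 and reversed in 1 (MFA1). Absolute depth is unknown, which limits what can be said of genes listed near 0.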

Other observations

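The tests of meiotic cells, of wild-type level and of listed 0s were chosen after the results were seen, as were the genes in the next paragraph.

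Genes outside the lists rose as well, and 130 of the 211 genes at least 2-fold higher belonged to no list. The middle sporulation list is not complete, and these unlisted genes include sporulation genes such as LDS1 and SPR2, named earlier. DAL80, a repressor of nitrogen catabolic genes, rose 10.5-fold from 5.90 ± 0.11 to 61.7 ± 1.91 FPKM (n = 2, limma adjusted p = 9.87e-05). The allantoin genes DAL1 and DAL4 rose 4.25- and 2.91-fold. SNZ1 and SNO1, of vitamin B6 synthesis, rose 5.27- and 2.59-fold. ARO9 and ARO10, of aromatic amino acid breakdown, rose 2.24- and 2.34-fold. HXT14 of the hexose transporter family went from 0.077 ± 0.033 to 27.8 ± 3.33 FPKM, and HXT10 from 0.687 ± 0.349 to 13.8 ± 1.60. EST1, a telomerase subunit gene, rose 3.63-fold from 10.4 ± 0.36 to 37.8 ± 1.05 FPKM. It lies beside BNA5, which rose too. The pair is in tandem with EST1 upstream, so reads running on from BNA5 would head away from EST1. Reads of antisense or overlapping transcripts are not separated.

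The genes at least 2-fold higher included 32 of the middle sporulation list. Meiotic cells of all stages in the deletion cultures would raise early meiotic genes about as much. The early median was 0.24 (bootstrap over genes, 95% limits -0.04 to 0.47) against 1.71 (0.995 to 2.17), at like wild-type levels (medians of 5.75 and 6.07 FPKM). This goes against such a mixture. Cells past the early stage need not raise early genes, so the comparison alone cannot exclude them. The design argues against meiotic cells of any stage. Both strains were of the alpha mating type, carried a replaced HMR locus and grew exponentially in rich glucose medium. A middle sporulation element, the site of Sum1 and Ndt80, lay within 500 bp upstream of 58 (32.6%) of the 178 such genes that are in R64 and could be searched (33 of the 211 are not) and 6.94% of other genes, an odds ratio of 6.48 (95% limits 4.57 to 9.10; Fisher's exact test, two-sided p = 8.32e-23). Outside the list the odds ratio was 4.82 (3.19 to 7.15). That set still holds unlisted sporulation genes such as LDS1 and SPR2, so it does not show the site acting beyond sporulation genes. Going by these odds ratios, loss of Sum1-Hst1 repression may account for part of the rise. Within the list 22 of 37 risers and 7 of 13 others had a site (Fisher's exact p = 0.754). The site did not separate them there, although so few others give the test little power. Which deacetylase matters stays open, since both were deleted together, and most of the searched genes had no such site.

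Of 246 subtelomeric genes listed 165 were tested, and these were called higher in 27.3% of cases against 5.98% of tested genes elsewhere. Reads shared between copies do not account for it, since among genes without a copy the odds ratio was 5.09 (95% limits 3.21 to 7.90). Subtelomeric genes also had lower wild-type levels, with a median of 12.3 against 43.8 FPKM. Random interior genes of like wild-type level, drawn within 20 level classes, were called higher in 14.5% of cases (central 95% of 10000 draws 9.7% to 20.0%). Level as matched by these classes may account for part of the excess but not all, and levels can still differ within a class. Genes at 0 in wild type, such as YOL166W-A, were tested only because of their deletion values. Genes within 10 kb of the end were called more often than those between 10 and 20 kb. The odds ratio was 4.68 (95% limits 2.15 to 10.5, Fisher's exact test, two-sided p = 2.29e-05). Loss of Sir2 silencing near telomeres may give this, which stays untested against loss of Hst1. The limits of both odds ratios, and this p, treat genes as independent. Genes at least 2-fold higher often lay side by side, as given below, so the limits may be too narrow and the p too small.

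Mating-type genes were listed at 0 in an alpha strain. Among names matched to R64, the only ones searched for copies, 119 were listed at 0 in all 4 libraries. Of these 98 (82.4%) had a near-identical copy, against 4.16% of the others. The odds ratio was 107.2 (95% limits 65.1 to 184, Fisher's exact test), so the read assignment may have given no value to some repeated sequence. It did not do so throughout, since 245 names with a near-identical copy were not at 0 in all 4 libraries. HMRA1, for which no near-identical copy was found, is not covered by this, but the labels give HMR as replaced in both strains, so a 0 for HMRA1 and HMRA2 needs no other account. No biological explanation was tested.

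Genes at least 2-fold higher lay side by side in 27 neighbouring pairs, against a median of 5 and a maximum of 15 in 10000 random draws of as many genes (permutation p = 0.0001, the smallest these draws can give). Without overlapping genes and at least 20 kb from an end, 19 pairs remained against a median of 4 and a maximum of 14. Of the 27 pairs 9 were divergent, 11 tandem and 7 convergent, against 1503, 2760 and 1502 of all neighbouring pairs, a difference that was not tested. One hypothesis is that neighbours may rise together through shared regulatory sequence or spreading transcription, which these files do not separate.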
